A study of Arabidopsis thaliana with 6 samples.

How the data were processed

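RNA-seq was available for 3 Col-0 and 3 mrg1 mrg2 libraries made from aerial parts of 12-day-old seedlings. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced on an Illumina HiSeq2000 as single-end reads of 50 bp, with a minimum read number per library. Per the submitters' processing notes, the genome build was TAIR10 and DESeq2 was used; the aligner, the counting tool and their settings are not given in the sources used here. The authors deposited 1 table of genes higher in the mutant and 1 of genes lower, and only these listed genes were used.

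The raw counts in both tables are whole numbers of reads per gene and library, per the file headers, and were not normalized before they were deposited. The p-value and the adjusted p-value (headed FDR) are those of the authors' test of mrg1 mrg2 against Col-0, and the largest adjusted p-value was 0.0497. The log2 fold change is the authors' value of mrg1 mrg2 over Col-0, per the file headers, and its sign was checked against the counts. Because genes that were not listed have no values here, library totals, and so the depth of each library, are unknown from the tables, and no new test over all genes was made. A count of calls adjusted over the list alone cannot be given for the gene lists, since their unlisted members have no p-value here.

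Size factors of the 6 libraries were recovered from the deposited tables by fitting the factors that turn the counts into the authors' log2 fold changes, over 350 genes with at least 50 counts. The fitted factors lay between 0.954 and 1.07, with bootstrap SD of at most 0.000660 (200 draws), and left a residual SD of 0.000659 on the log2 scale, against 0.00920 with equal factors. Normalized counts are raw counts divided by these factors, given as mean ± SD over the 3 libraries of a genotype. Fold changes, p-values and adjusted p-values of single genes are quoted from the authors' table and carry no SD. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so none is quoted for single genes. A fold change against a group with no reads is a lower bound against 3 counts over the group, and such bounds cover counting error only.

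From the ranks that link p-values to adjusted p-values under the Benjamini-Hochberg procedure, the authors' test was inferred to have covered 22995 genes. The last listed gene would then rank 747, so that 195 genes within the listed range of adjusted p-values are not listed and were not analysed here.

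Replicate pairs of a genotype differed by 13.4 to 38.3 times the chi-square per degree of freedom of counting noise, so none was a repeated library. Col-0 and mutant libraries share replicate numbers. Deviations from the genotype means correlated across 435 genes with r = 0.40, 0.55 and 0.32 for libraries with the same number, and with -0.42 to 0.02 for other pairs; the numbers were therefore taken to pair the libraries, from these correlations. Genes are not independent replicates in such correlations. P-values of the refits without a block rest on the spread between the libraries of a genotype over the 3 experiments. Those with replicate number as a block rest on the spread of the genotype difference between experiments. No covariate of the authors' test is known here, so its p-values may ignore the pairing. The Fisher, binomial and permutation tests take genes as units and measure neither spread.

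The listed genes were refitted with edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 in R 4.3.3, with the recovered size factors, with and without replicate number as a block, and without each library in turn. A gene passed at p of at most 0.00161, the largest p-value in the deposited tables. Since the listed genes were selected for a difference, their spread is not that of all genes, and the refits describe only how the calls depend on libraries and model. The edgeR fit was tested on simulated counts for 542 of the genes: it recovered 8.96% of the genes changed 1.5-fold, 68.7% of those changed 2-fold and 90.9% of those changed 4-fold, and called 0 of 342 unchanged genes.

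Before the data were examined, 16 gene lists with 266 entries (259 genes) were fixed, and each was tested for over-representation among higher and lower genes with Fisher's exact test, one-sided, against 27444 nuclear protein-coding genes, with Benjamini-Hochberg adjustment over 32 tests. The genes the authors tested are fewer than this background, and the smallest background that kept each call was 4900 genes for rapid stress, 13600 for cold, 16000 for immunity, 16800 for the MRG list and 19100 for abscisic acid. Lists share members: WRKY33 and WRKY40 are in the rapid stress and immunity lists, and ZAT10 in the rapid stress and cold lists. Fold sizes were compared by permutation tests with 100000 resamples, and neighbours, chromosomes and gene lengths with 10000 random draws. Gene positions are from the TAIR10.1 annotation, whose strand matched the authors' table for 549 of 549 genes compared; 3 mitochondrial genes had no reference row.

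The genes named were fixed by rule. They were MRG1, MRG2 and SOC1, and the 10 named genes with the largest and the 6 with the most negative log2 fold change. Also named were the 3 listed members of each gene list with the largest change, and every listed member of the flowering and clock lists. This gave 34 listed genes, and 21 higher and 5 lower genes without a gene name were passed over. The remaining members of the enriched lists (CBF2, WRKY70, P5CSA, ZAT6, ERF1A, ERF5 and ERF6), the neighbours of MRG1 and the genes in the closing observations were named after their values were seen. Alternatives covered adjusted p and fold cutoffs, genes with low counts, backgrounds, windows, left-out libraries and the replicate block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for all other steps.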

Results

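RNA was measured in the aerial parts of 12-day-old Arabidopsis thaliana seedlings of 2 genotypes, the Col-0 wild type and a mutant in both MRG1 and MRG2. The MRG proteins are chromodomain proteins that bind methylated lysine 36 of histone H3 and work with histone acetyltransferases. Plants grew on soil at 22 °C under 16 h of light and 8 h of darkness and were collected 8 h after lights on. Each genotype was represented by 3 libraries, and the labels state that they came from 3 independent experiments. The values used were raw read counts in 6 libraries for the 552 genes that the authors listed as differing between the genotypes. Library totals were not used here, so sequencing depth per sample is known only from the labels, which state a minimum read number per library. Counts summed over the listed genes ran from 194996 to 253738 in Col-0 and from 372415 to 432369 in mrg1 mrg2; these sums reflect the choice of genes and are not depths.

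The comparison asked which transcripts depended on the MRG proteins around the transition to flowering, with the floral integrator SOC1 and abiotic stress genes as the stated interest of the study. The mutated gene MRG2 (AT1G02740, chromosome 1, 599330 to 602199, 10 exons) gave 406 ± 20.5 normalized counts in Col-0 and 133 ± 55.6 in mrg1 mrg2 (SD, n = 3 each), a 3.06-fold lower level. MRG2 fell by 1.61 on the log2 scale in the authors' deposited table, with an adjusted p of 4.46e-06. MRG2 counts were lower in each mutant library than in each Col-0 library, which matches the labels for MRG2. MRG1 (AT4G37280, chromosome 4, 17546577 to 17549559) and SOC1 were not among the listed genes, so no value is given for either. The MRG1 part of the mutant label was therefore not checked in the RNA.

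Most listed genes had more RNA in the mutant. The authors' deposited table gave 531 genes as higher in mrg1 mrg2 and 21 as lower, so that 96.2% of the 552 listed genes were higher (exact binomial 95% interval 94.2 to 97.6%, exact two-sided p = 7.16e-129 against an even split). The interval and p treat genes as independent, the 2 lists have different smallest changes, and 195 further genes within the listed range of adjusted p are not analysed here. The higher genes comprised 506 nuclear protein-coding genes, 22 noncoding RNA genes and 3 mitochondrial genes, and the 21 lower genes were all nuclear and protein-coding. The median change in the authors' deposited table was 1.08 on the log2 scale for higher genes, a 2.12-fold difference, and 3.10-fold for lower genes. The median of the higher genes was also 1.08 with the 4 genes that had no reads in any Col-0 library set at their lower bound. The smallest change listed was 1.51-fold among higher genes and 2.09-fold among lower genes in the authors' deposited table. There, 224 of the 531 higher genes and 0 of the 21 lower genes lay below 1 on the log2 scale (Fisher's exact test, two-sided p = 1.56e-05); at 1 or above the lists held 307 and 21 genes. The median size of the log2 change was larger in lower genes by 0.55 (permutation test, two-sided p = 0.00185), and by 0.27 with both lists limited to changes of at least 1 (p = 0.105). If the 2 lists were cut at different folds, the share below 1 and the difference of 0.55 could follow from the cutoffs alone. No conclusion on the size of the changes is drawn from them. The 3 libraries of each genotype did not overlap for 530 of the higher and 20 of the lower genes, where chance gives 10%; these genes had been selected for a difference.

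**Figure D1:**
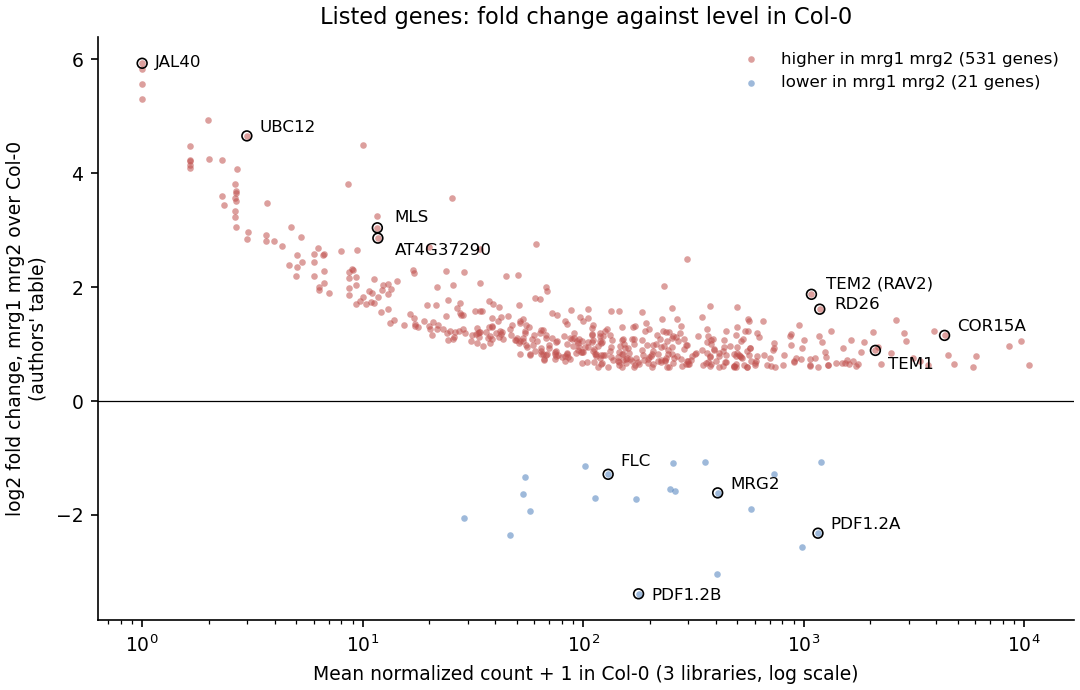
Log2 fold change of mrg1 mrg2 over Col-0 from the authors' deposited table (vertical axis) against the mean normalized count plus 1 in Col-0 over 3 libraries (horizontal axis, log scale). Each point is 1 of the 531 higher (red) or 21 lower (blue) genes, circled points are named genes, and no lower gene lies closer to 0 than -1.06.

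Among genes with a gene symbol, the largest increases were in genes with little RNA in Col-0. JAL40 (AT5G28520), which encodes a jacalin-related lectin, had 0 counts in every Col-0 library and 11.2 ± 9.24 normalized counts in the mutant (SD, n = 3), at least 11.2-fold higher against a floor of 3 counts over the Col-0 group. UBC12 (AT3G08700), a ubiquitin-conjugating enzyme gene, went from 1.98 ± 0.959 to 50.3 ± 7.46 normalized counts (SD, n = 3 each). MLS (AT5G03860, chromosome 5, 1032099 to 1034973), which encodes malate synthase of the glyoxylate cycle, went from 10.7 ± 2.96 to 87.7 ± 12.0 normalized counts (SD, n = 3 each). The log2 changes of UBC12 and MLS were 4.65 and 3.04 in the authors' deposited table, with adjusted p of 8.67e-09 and 7.19e-13. The next largest log2 changes of genes with a symbol, in the authors' deposited table, apart from MLS, were TULP5 at 4.26, SYP24 at 4.23, the mitochondrial ORF110B at 4.23, CYP705A25 at 3.80, LECRK51 at 3.43, ATCNGC14 at 3.25 and KIN14P at 3.05. Col-0 means were below 10 normalized counts for 68 of the 531 higher genes, so counting error is large in these fold changes.

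Plant defensin genes, which are induced by jasmonate and ethylene, were 4 of the 5 genes with the largest decreases. PDF1.2A (AT5G44420, chromosome 5, 17906968 to 17907638) went from 1160 ± 436 normalized counts in Col-0 to 232 ± 108 in the mutant (SD, n = 3 each), and PDF1.2C, PDF1.3 and PDF1.2B were lower as well. They fell by 2.32, 2.57, 3.04 and 3.38 on the log2 scale in the authors' deposited table, with adjusted p between 3.54e-09 and 2.38e-06. These 4 genes have very similar sequences and reads were 50 bp long, so the split of reads among them is uncertain. ATGRP9, encoding a glycine-rich protein, and UGT79B3, encoding a glycosyltransferase, fell by 2.35 and 1.63 on the log2 scale in the authors' deposited table. PDF1.2A was the only listed member of the 26 genes fixed as jasmonate and wounding genes (Fisher's exact test, one-sided adjusted p = 0.0970 for lower genes), and 0 of the 26 were higher.

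Of 28 flowering time regulators, 2 rose, 1 fell and 25 were not listed. FLC (AT5G10140, chromosome 5, 3173382 to 3179448), a MADS-domain repressor of flowering, went from 129 ± 12.8 to 52.7 ± 10.4 normalized counts (SD, n = 3 each), a 2.44-fold lower level. TEM1 (AT1G25560) and TEM2 (RAV2, AT1G68840), related repressors of the florigen gene FT, were both higher. TEM1 rose from 2113 ± 253 to 3913 ± 692 normalized counts and TEM2 from 1083 ± 597 to 3969 ± 467 (SD, n = 3 each). The log2 changes of FLC, TEM1 and TEM2 in the authors' deposited table were -1.29, 0.89 and 1.87, with adjusted p of 4.26e-05, 7.72e-05 and 4.45e-05. The list as a whole was not enriched among higher genes (Fisher's exact test, one-sided adjusted p = 0.333) or lower genes (adjusted p = 0.0970). Of the 18 genes fixed beforehand as circadian clock genes, 0 were listed. TEM1 and TEM2 both had their highest Col-0 count in replicate 1, with a median log2 gap of 0.75 over Col-0 replicates 2 and 3.

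**Figure D2:**
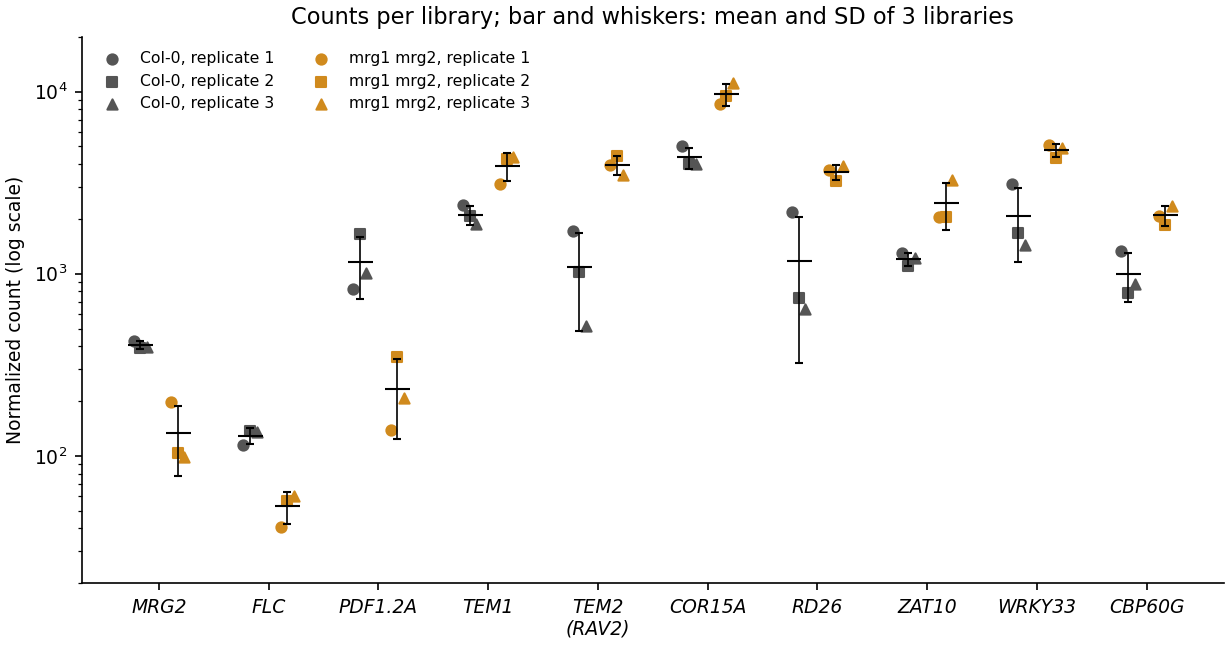
Normalized counts (log scale) of 10 named genes in each of the 3 Col-0 (grey) and 3 mrg1 mrg2 (orange) libraries, with symbols for replicate number, horizontal bars for means and whiskers for SD. Libraries of the 2 genotypes do not overlap for any of the 10 genes. Col-0 replicate 1 lies above the other Col-0 libraries for genes that include TEM1, TEM2, RD26, WRKY33 and CBP60G.

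Rapid stress and touch response genes were over-represented among the higher genes. Of the 28 genes on this list, 9 were higher (32.1%, against 1.84% of 27444 nuclear protein-coding genes), 0 were lower and 19 were not listed (Fisher's exact test, one-sided adjusted p = 3.71e-08). SZF1 (AT3G55980), a zinc finger protein gene induced by salt, went from 2611 ± 1224 to 6978 ± 2174 normalized counts (SD, n = 3 each). WRKY33 (AT2G38470), a transcription factor of the defence response, went from 2068 ± 904 to 4763 ± 409, and PUMP4 (AT4G24570), a mitochondrial carrier gene, from 1170 ± 441 to 2589 ± 891 normalized counts (SD, n = 3 each). The log2 changes of SZF1 and PUMP4 in the authors' deposited table were 1.42 and 1.15, with adjusted p of 0.00270 and 0.0224; WRKY33, 2.30-fold higher in normalized counts, had an adjusted p of 0.00175 there. ZAT10, ZAT6, WRKY40, ERF1A, ERF5 and ERF6, all genes of transcription factors, were the other higher members. Col-0 replicate 1 exceeded both other Col-0 libraries for 6 of the 9 members and for 254 of all 531 higher genes. The median log2 gap was 0.67 in the 9 members, compared with 0.13 over all 531 higher genes. The fold changes of the 9 members did not differ from those of the other higher genes by more than chance (difference in median log2 change -0.05, permutation test, two-sided p = 0.749). With higher genes limited to those that also passed a refit, the list passed with DESeq2 (adjusted p = 7.38e-09) and with edgeR and a replicate block (2.11e-06), did not pass with edgeR on all libraries (0.271), and with each library left out ranged from 2.36e-06 to 1 (Fisher's exact test, one-sided).

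Cold-regulated genes were the next most enriched list. Of 17 genes, 4 were higher (adjusted p = 0.00359, Fisher's exact test, one-sided), 0 were lower and 13 were not listed. ZAT10 is shared with the rapid stress list, and the cold list was not tested without it. COR15A (AT2G42540, chromosome 2, 17710441 to 17712330), which encodes a chloroplast protein that protects membranes during freezing, rose from 4351 ± 573 to 9669 ± 1307 normalized counts (SD, n = 3 each). ZAT10 went from 1203 ± 98.6 to 2458 ± 709, and KIN1 from 146 ± 30.1 to 285 ± 66.8 normalized counts (SD, n = 3 each). In the authors' deposited table the log2 changes were 1.15 for COR15A, 1.03 for ZAT10, 0.96 for KIN1 and 0.94 for CBF2, with adjusted p of 2.13e-10, 0.000251, 0.00686 and 0.0116. Col-0 replicate 1 was above both other Col-0 libraries for 3 of the 4 members, with a median log2 gap of 0.24, and for 254 of all 531 higher genes. With higher genes restricted to log2 changes of at least 1, the list no longer passed the test (adjusted p = 0.110), nor did it with genes that passed edgeR with a replicate block (0.113) or without Col-0 replicate 2 or 3 or mutant replicate 2 or 3 (0.703 to 1).

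Salicylic acid and immunity genes and abscisic acid and water deficit genes were also enriched among the higher genes. Of 22 immunity genes, 4 were higher (adjusted p = 0.00684, Fisher's exact test, one-sided) and 0 lower: CBP60G (AT5G26920), a regulator of salicylic acid synthesis, WRKY70, and WRKY33 and WRKY40, which are shared with the rapid stress list. No test without the shared genes was made, so the immunity list is not separate evidence from the rapid stress list. CBP60G went from 997 ± 294 to 2097 ± 264 normalized counts, and WRKY40 from 624 ± 336 to 1356 ± 208 (SD, n = 3 each). Of 30 abscisic acid and water deficit genes, 4 were higher (adjusted p = 0.0171, Fisher's exact test, one-sided) and 0 lower. RD26 (AT4G27410, chromosome 4, 13707192 to 13709170), a NAC transcription factor gene, rose from 1182 ± 858 to 3609 ± 349 normalized counts (SD, n = 3 each). SAG113, a protein phosphatase gene, went from 172 ± 63.4 to 428 ± 117, and ATHB-12, a homeodomain-leucine zipper gene, from 217 ± 6.84 to 354 ± 65.3 normalized counts (SD, n = 3 each). P5CSA, a gene of proline synthesis, was the remaining member. In the authors' deposited table the log2 changes of CBP60G, WRKY40, RD26, SAG113 and ATHB-12 were 1.07, 1.12, 1.61, 1.32 and 0.71. Col-0 replicate 1 was above both other Col-0 libraries for 3 of the 4 immunity members and 4 of the 4 abscisic acid members, with median log2 gaps of 0.85 and 0.62. Over all 531 higher genes this held for 254. The abscisic acid list did not pass when higher genes were limited to those that also passed any of the refits (adjusted p = 0.0511 to 1), with a background of 0.5 times the size (0.150) or with log2 changes of at least 1 (0.183); the immunity list did not pass with that smaller background (0.0630), nor with genes that passed edgeR on all libraries (0.999), with a replicate block (0.157) or with any library but Col-0 replicate 1 left out (1 in each of these 5 refits). The immunity list did pass with genes that passed edgeR without Col-0 replicate 1 (adjusted p = 0.0277, Fisher's exact test, one-sided), DESeq2 (0.00342) or DESeq2 with the block (0.00227).

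**Figure D3:**
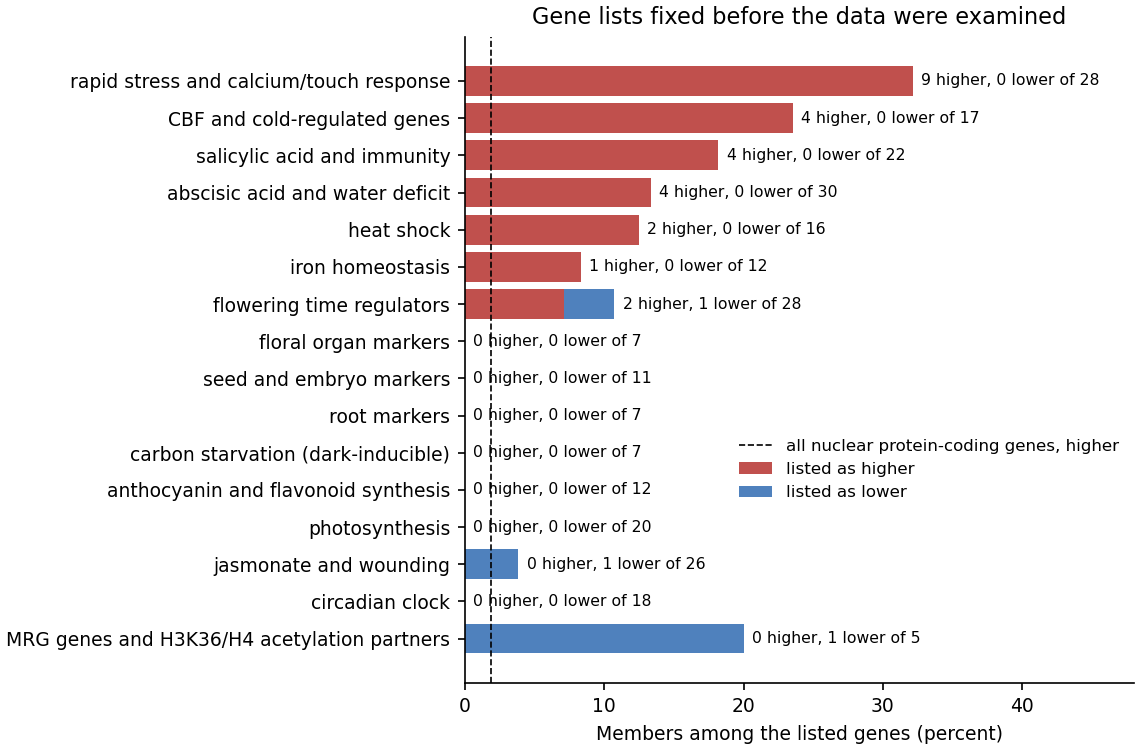
Percent of the members of each of the 16 gene lists that the authors listed as higher (red) or lower (blue) in mrg1 mrg2, with the counts beside each bar. The dashed line marks the 1.84% of nuclear protein-coding genes listed as higher, and the rapid stress list stands highest at 32.1%.

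Other lists held few or no listed genes. Of 16 heat shock genes, 2 were higher (adjusted p = 0.137, Fisher's exact test, one-sided), namely HSP15.7 with 66.9 ± 8.61 against 150 ± 20.4 and HSP18.1 with 56.4 ± 4.89 against 99.7 ± 4.46 normalized counts (SD, n = 3 each). Of 12 iron homeostasis genes, 1 was higher (adjusted p = 0.641), the ferric reductase gene FRO3, with 983 ± 191 against 1870 ± 334 normalized counts (SD, n = 3 each). HSP15.7, HSP18.1 and FRO3 had log2 changes of 1.17, 0.82 and 0.93 in the authors' deposited table. None of the 20 photosynthesis, 12 anthocyanin, 7 carbon starvation, 7 root, 11 seed or 7 floral organ genes was listed. The list of the MRG genes and their partners had 1 lower member of 5 (adjusted p = 0.0245), MRG2, which is the mutated gene and not independent evidence.

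The deposited counts of the listed genes were refitted to see how the calls depended on the libraries. At the largest p that the authors listed, 0.00161, edgeR kept 374 higher and 18 lower genes and DESeq2 kept 439 and 21. In the simulated counts edgeR recovered 8.96% of 1.5-fold and 68.7% of 2-fold changes, so a gene that fails a refit may still differ. The edgeR count of higher genes was 238 without Col-0 replicate 2, 249 without Col-0 replicate 3 and 190 without mutant replicate 2, and no listed gene changed sign. With replicate number as a block, edgeR kept 383 higher and 19 lower genes, but not the same ones: 46 of the 374 higher genes were lost and 55 others gained. Of the flowering genes, FLC and TEM2 passed edgeR with and without the block and TEM1 did not; TEM1 passed edgeR only without Col-0 replicate 1 and passed DESeq2 with and without the block. Of the rapid stress members edgeR kept 2 without the block and 7 with it, of the cold members 4 and 2, and of the immunity members 1 and 2. Without Col-0 replicate 1, edgeR kept 7 rapid stress, 3 cold, 3 immunity and 2 abscisic acid members; without Col-0 replicate 3 it kept 0 members of each of these lists. With each of the other 4 libraries left out in turn, edgeR kept 0 to 4 rapid stress, 0 to 4 cold, 0 immunity and 0 to 1 abscisic acid members. DESeq2 kept 9 rapid stress, 4 cold, 4 immunity and 2 abscisic acid members without the block.

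Listed genes lay next to each other more often than random genes. Among 527 nuclear protein-coding listed genes there were 25 adjacent pairs, against 10.07 ± 3.13 (SD) in 10000 random draws of as many genes (permutation test, one-sided p = 0.0001, the smallest these draws can give). With nearby genes whose symbols differ only in their final number or letter counted once, there were 16 pairs (permutation test, one-sided p = 0.0371). Draws were made from all nuclear protein-coding genes and not only from those the authors tested. No smaller background was run, so the number of pairs by chance may be understated and the p-values too small. Relatives known only by a gene code or with unlike symbols were not merged, so the remaining pairs can still be tandem duplicates. Within 1 Mb of MRG1 or MRG2, 25 of 1039 genes were listed (2.41%, against 1.90% elsewhere; Fisher's exact test, two-sided p = 0.248). Over the 5 nuclear chromosomes the listed genes did not depart from the numbers of protein-coding genes (chi-square 7.05, permutation p = 0.132), but they did with adjusted p below 0.01, where chromosome 1 held 33.5% against 26.1% expected (chi-square 10.5, permutation p = 0.0297). Higher genes had a median of 2 exons against 4 in all nuclear protein-coding genes (permutation p = 0.0002), whereas their median transcript length, 1544 nt against 1516.5 nt, did not differ by more than chance (permutation p = 0.528). The 21 lower genes had a median of 2 exons as well, which with so few genes did not pass (permutation p = 0.268).

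The region around MRG1 on chromosome 4 held several higher genes. Of the 10 protein-coding genes nearest to MRG1, 5 on each side, 4 were higher and 0 were lower, while 0 of the 10 around MRG2 were listed. AT4G37290 (17549607 to 17550257), 48 bp from MRG1, went from 10.7 ± 4.37 to 77.6 ± 11.0 normalized counts, and AT4G37295 (17553310 to 17554105) from 8.00 ± 3.95 to 39.6 ± 12.2 (SD, n = 3 each). MYB73 (17540490 to 17541799), a MYB transcription factor gene, went from 2853 ± 967 to 6551 ± 2454, and the cytochrome P450 gene CYP81H1 (17555899 to 17559104) from 1497 ± 183 to 2366 ± 256 normalized counts (SD, n = 3 each). The log2 changes of AT4G37290, AT4G37295 and CYP81H1 in the authors' deposited table were 2.86, 2.30 and 0.66, with adjusted p of 7.40e-10, 0.00133 and 0.000725; MYB73, 2.30-fold higher in normalized counts, had an adjusted p of 0.00675 there. The genes of this region were chosen after their values were seen.

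**Figure D4:**
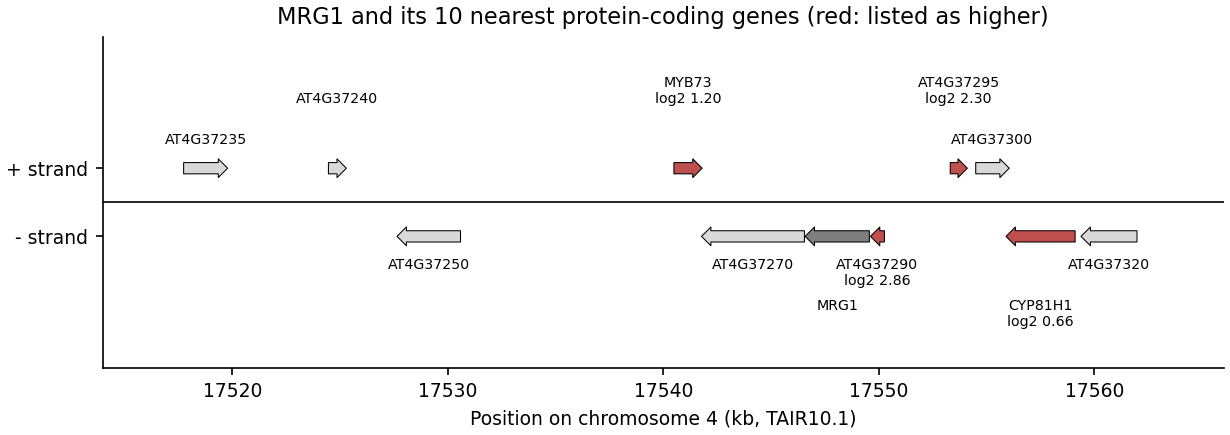
Map of MRG1 (dark grey) and its 10 nearest protein-coding genes by strand, with position on chromosome 4 in kb (horizontal axis, TAIR10.1). Arrows point in the direction of transcription, and the 4 genes in red were listed as higher, with log2 changes of 0.66 to 2.86 in the authors' deposited table.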

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

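The refits (their left-out libraries and block included), the enrichments with the inferred background or with genes passing a refit, and the fold comparison at 1 or above in both lists were chosen after the data were seen. With adjusted p below 0.01 and below 0.001 there were 334 and 203 higher genes, and 13 lower genes below 0.001; with log2 changes of at least 1 and 1.5 there were 307 and 129 higher genes. Stricter cutoffs leave fewer genes by construction. Without each library in turn, 500 to 516 higher and 18 to 20 lower genes kept a fold at or above the smallest listed, and the edgeR refit kept 190 to 390 higher and 14 to 19 lower genes, with 238 without Col-0 replicate 2, 249 without Col-0 replicate 3 and 190 without mutant replicate 2. With the replicate block, edgeR kept 383 and 19 and DESeq2 393 and 21, so no count of calls over all listed genes moved by over 1.5 times. Single calls did change: of the higher genes edgeR lost 46 and gained 55, and DESeq2 lost 62 and gained 16; of the lower genes edgeR lost 1 and gained 2. With the background halved, adjusted p was 0.150 for the abscisic acid list and 0.0630 for the immunity list and for the MRG list (lower genes). With log2 changes of at least 1 it was 0.110 for the cold list and 0.183 for the abscisic acid list. With genes passing edgeR on all libraries it was 0.271 for the rapid stress, 1 for the abscisic acid, 0.999 for the immunity and 0.0524 for the MRG list, and with the block 0.113 for the cold, 1 for the abscisic acid, 0.157 for the immunity and 0.0553 for the MRG list. With DESeq2 it was 0.308 for the abscisic acid list, and 0.0511 with the block. With genes passing edgeR without each library in turn it ranged from 2.36e-06 to 1 for the rapid stress, 0.000536 to 1 for the cold, 0.249 to 1 for the abscisic acid, 0.0277 to 1 for the immunity and 0.0277 to 0.105 for the MRG list. Within these ranges, without Col-0 replicate 2 it was 0.703 for the cold, 0.830 for the rapid stress and 0.0932 for the MRG list, without mutant replicate 2 0.966 for the abscisic acid and 0.0874 for the MRG list, and without mutant replicate 3 0.0815 for the MRG list. Of 15 alternatives each, the rapid stress list passed 10, the cold list 9, the MRG list 8, the immunity list 7 and the abscisic acid list 3. Lower genes had the larger median log2 change by 0.55 (permutation p = 0.00185), and by 0.27 (p = 0.105) at 1 or above in both lists. The chromosome chi-square rose to 10.5 (p = 0.0297) with adjusted p below 0.01. The difference in median log2 change of rapid stress members turned to 0.19 (permutation p = 0.172) against genes of similar level, and that of higher genes in length to -7.5 nt (permutation p = 0.879) for coding length; neither passed. Except for cutoffs, the cause of these shifts was not tested. For the other 153 alternative values, counts stayed within 1.5 times the main count and tested values kept their side of the threshold. Among them, differences between medians and the odds ratios near the MRG loci also kept their direction, while direction was not compared for the gene lists. The 153 values include all alternatives of the flowering, heat shock, iron and jasmonate lists, which passed in no setting. The planned pseudocount alternative was not run, since the tables hold counts. Depth limits the 68 higher genes with Col-0 means below 10.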

Other observations

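The MRG1 region, name stem, letter-order and cutoff tests and the intervals of the promoter odds ratios were chosen after the results they bear on were seen; the promoter site, pseudogene and length tests were set before their own results were seen. NAC transcription factor genes were enriched, with 10 of 100 higher in the mutant (Fisher's exact test, one-sided adjusted p = 0.00379 over 232 name stems of at least 15 genes, taken from symbols and synonyms, some of them clone names and not gene families). NAC029, a regulator of leaf senescence, rose by 2.76 on the log2 scale, NAC92 by 1.23, NAC003 by 1.11 and NAC002 by 0.78 in the authors' deposited table. Their adjusted p there were 0.0470, 0.00223, 2.58e-06 and 7.16e-06, so the largest of these changes was the weakest call. Cytochrome P450 genes followed, with 14 of 250 higher (adjusted p = 0.0287). No alternative background, cutoff or refit was applied to the name stem tests. SFH1 (AT4G34580), a phosphatidylinositol transfer protein gene, had the smallest listed p and went from 294 ± 27.3 to 1648 ± 15.6 normalized counts (SD, n = 3 each), a 5.60-fold difference. The noncoding RNA gene AT1G67105 reached 203 ± 37.3 normalized counts in the mutant (SD, n = 3), a 22.6-fold higher level than in Col-0.

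Other higher genes were picked from the list by hand, and no group test was made on them. PHE1, an imprinted MADS-domain gene of the endosperm, was 6.38-fold higher, with 210 ± 19.7 normalized counts in the mutant, and its close relative PHE2 went from 8.35 ± 1.28 to 34.1 ± 4.50 (SD, n = 3 each). The log2 changes in the authors' deposited table were 2.67 for PHE1, 2.27 for the MADS-domain gene AGL102, 2.64 for APUM9 and 1.60 for QQS, an orphan gene affecting starch content. The DNA demethylase gene DML3 rose by 1.37 and the chromatin remodeller gene CLSY3 by 0.97 in the authors' deposited table, with adjusted p of 1.08e-18 and 0.0469. LSU1, LSU3 and SDI1, which are induced by sulfur deficiency, rose by 1.27, 1.29 and 1.07 in the authors' deposited table. Of the genes fixed beforehand, 0 of 11 seed and embryo markers and 0 of 7 floral organ markers were higher.

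The cluster of 4 higher genes among the 10 nearest to MRG1 was weighed against chance and read-through. Windows around 10000 random protein-coding genes held as many listed genes in 2 cases and 3 of all 27444 windows did, but these 3 hold the same 4 genes, and the window was picked after the cluster was noticed. With the best window of 1 to 20 genes on each side of every gene, MRG1 alone (1 of 27444 genes) reached its hypergeometric p, and 4 did, 1 of them at another locus, with the central gene counted; this argues against chance placement at a gene fixed by the design, although the cluster was 1 of several features looked at and within 1 Mb 13 of 567 genes were listed (Fisher's exact test, two-sided p = 0.533). All 4 neighbours lie on the other strand or upstream of MRG1, which argues against transcription running on from MRG1. A candidate explanation is a local effect of the mutation or of the loss of MRG1 itself; the position of the mutation was not used here, and this was not tested.

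Higher genes with Col-0 means below 10 normalized counts were weighed for location and length. The 61 protein-coding ones had 3.41 annotated pseudogenes within 50 kb on average against 2.03 for the other 445, a difference of 1.38 (one-sided permutation p = 0.00476). Their median transcript length was 1308 nt against 1584 nt, a difference of -276 nt (two-sided permutation p = 0.0117). Counts were not corrected for transcript length, so a group chosen for low counts favours short genes, and no conclusion is drawn from the length difference. The pseudogene difference could arise if weakly expressed genes in pseudogene-rich regions gained RNA in the mutant. However, weakly expressed genes that were not listed have no values here, so both features may belong to weakly expressed genes in general.

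Promoters of the 506 higher protein-coding genes were searched over 500 bp for 4 transcription factor sites. The W-box, bound by WRKY factors, was present in 52.4% against 45.0% of other genes (odds ratio 1.34, one-sided Fisher's exact test, adjusted p = 0.00245). The MADS-domain CArG box (odds ratio 1.19, adjusted p = 0.311), the CBF site (0.846, adjusted p = 0.937) and the abscisic acid response element (1.17, adjusted p = 0.311) did not pass. For the CArG box and the abscisic acid element the 95% intervals of the odds ratio reach 1.78 and 1.56, so the bound set beforehand, an adjusted p of 0.05 or more, was too weak to exclude them; the CBF site was not more frequent (18.8% against 21.5%), and its interval, 0.675 to 1.06, argues against an enrichment as large as that of the W-box but not against a slight one. Higher genes had less GC (30.3% against 31.8%), but 2 of 359 other orders of the W-box letters gave as large an odds ratio, which argues against composition as the whole cause; of 72 WRKY genes 4 were higher (Fisher's exact test, one-sided adjusted p = 0.681), and no biological explanation was tested.

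The excess of higher over lower genes held with the cutoffs considered: the 21 lower genes plus all 195 unlisted genes in the listed range of adjusted p make 216, fewer than the 531 higher genes. In the edgeR refit of the listed genes, the real split passed 392 genes and the highest of the other splits 1; with 10 splits of the 6 libraries, the real one included (1 split as large), a share under 0.05 cannot be reached, and the genes were selected on the real split.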
